A study of Homo sapiens with 2 samples.

How the data were processed

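Total RNA of BFTC 905 cells, extracted with TRIzol per the labels' protocols, was sequenced in 2 libraries, 1 from cells with the pcDNA3.1 vector and 1 from cells with the ANGPTL4 plasmid, both selected with G418. Each library was assigned to its group by the transfection named in its label. The values are RPKM (reads scaled to exon length and library size) as the authors deposited them, 1 value per gene row, per the file headers. The genome build was hg19, per the submitters' processing notes. The aligner, the counting program, the annotation release, the read length, the handling of reads that match several loci and the use of strand were not given in the sources used here. RPKM divides by the reads of the whole library, so a few very abundant genes lower all others, and genes that overlap or resemble each other can gain or lose reads by rules that are not known here.

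Both tables held 57773 rows in the same order. Rows with the same gene symbol were summed, which left 55773 symbols, and 27 names that a spreadsheet had turned into dates were kept as they stood and not translated. Region starts in the tables count from 0 and are printed here counting from 1. Gene type, exon length and GC content were looked up by symbol in GENCODE release 29, and none of its coordinates were used, since it follows another build.

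Depth was worked out from the RPKM values. In each library a total was sought at which the values of genes with a single exon, and of the 13 mitochondrial genes, became whole reads (tolerance 0.0001). This gave 6572767 reads for the vector control and 3233596 for ANGPTL4. Of 1378 and 1123 values of rows shorter than 3 kb, taken as single exons, 300 and 278 became whole, among them all 13 mitochondrial genes. The best other totals nearby, 1 read away, made 271 and 251 whole and none of the 13. For each row the exon length was the whole number of bases at which both libraries gave whole reads, taking the candidate nearest the GENCODE exon length. The tolerance for this step rose with length and reads. A length was settled for 14954 of 18483 rows above 0, or 80.9%. For the others the smallest such length was used, so that their reads are minimum numbers and their intervals are, if anything, too wide. Intervals of a ratio are exact 95% intervals from the reads of both libraries given both depths, and cover counting error only. The share of mitochondrial reads has a Wilson interval, which likewise covers counting error only.

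The log2 ratio is log2((RPKM + 1) in the ANGPTL4 library / (RPKM + 1) in the control library), with a pseudocount of 1, which understates the difference of low genes. Genes with at least 1 RPKM in at least 1 library were called measured, and a difference of at least 2-fold on this scale was the size rule. With 1 library per group no test between groups can be made. For each of 46 gene lists, the median log2 ratio of its measured members was placed as a percentile among 10000 random lists of the same size drawn from the same 20 bins of mean expression, and a list stood apart below percentile 1 or above percentile 99. Lists with fewer than 5 measured members got no percentile. No correction for the number of lists was made, so a list near these limits can pass them by chance. The size rule, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined.

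The text names ANGPTL4, the 12 genes with the highest and the 12 with the lowest log2 ratio among those with at least 10 RPKM in a library, and for each list the 2 members at either end, leaving out list members that differ by under 1.5-fold on the log2(RPKM + 1) scale. Some of these smaller differences are also given, as are other members of marker lists. Small RNAs and rows without a gene symbol were left out of the first part of the rule. Some genes that the rule selects are not reported here. Clone-based names such as RP11-3P17.5 were read as rows without a symbol.

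The procedures were tested on simulated libraries of 13522 genes, simulated ANGPTL4 against simulated vector control. These were drawn at lower depths than those of the 2 libraries, with exon lengths partly drawn at random. The changed genes were drawn from those with at least 5 RPKM in the control library, so detection at lower levels was not tested. The size rule found 98.0% of 50 genes raised 2.5-fold, 100% of 50 raised 4-fold, 78.0% of 50 lowered to 0.4 and 100% of 50 lowered to 0.25. It called 0.495% of unchanged genes. A list of 25 genes shifted by 0.5 on the log2 scale reached percentile 100 and an unchanged list percentile 77.2. Reads were recovered exactly for 1480 of 1500 simulated rows, and the others were left unsettled. The reference length was set close to the true length for every simulated row. How well GENCODE lengths settle the reads of real rows was therefore not tested. The alternatives were pseudocounts of 0.1 and 5, no minimum and a minimum of 5 RPKM, centring on the median gene, upper-quartile scaling, rescaling to a fixed total with and without mitochondrial, ribosomal protein and small RNA genes, the highest row per symbol, fold limits of 1.5 and 4, intervals of the 2 libraries that do not overlap, and random lists without matching. Counts over nuclear protein-coding genes alone and list medians corrected for exon length and GC content were added after the data were seen. Chromosomal blocks were sought as running medians over 25 neighbouring genes, against 1000 shuffles of gene order. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.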

Results

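Gene expression was measured by RNA sequencing of total RNA from BFTC 905, an established human cell line derived from a urothelial carcinoma of the bladder. The vector control library came from cells stably carrying the empty pcDNA3.1 plasmid, and the ANGPTL4 library came from cells stably carrying a plasmid that expresses ANGPTL4, a secreted protein that inhibits lipoprotein lipase. There was 1 library per group, so no difference given here has a replicate check, no p-value was computed, and each statement compares these 2 libraries and not the conditions. Values are RPKM as the authors deposited them. The RPKM steps corresponded to 6572767 reads in the vector control library and 3233596 reads in the ANGPTL4 library, a 2.03-fold difference in depth. Values above 0 were listed for 17674 genes in the control and 16372 genes in the ANGPTL4 library. On a transcript of 2 kb, 1 read equalled 0.0761 RPKM in the control library and 0.155 RPKM in the ANGPTL4 library. The 95% intervals of ratios and of read shares given here cover counting error only and not differences between cultures or library preparations.

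The comparison asked which genes differ in a bladder carcinoma line with little ANGPTL4 of its own once ANGPTL4 is expressed from a plasmid. ANGPTL4 (chromosome 19, 8428173 to 8439257, hg19, value over the annotated exons) was the gene with the largest log2 ratio among all 11802 measured genes. Its level was 3.92 RPKM in the vector control library and 91.2 RPKM in the ANGPTL4 library. The ratio was 23.2 (95% interval 18.0 to 30.5, from 64 and 732 reads), or 4.23 on the log2(RPKM + 1) scale. Reads from the plasmid and from the chromosomal gene are not separated in these values. Of the 11 members of the angiopoietin-like family list, 10 were present under the symbols used. None of these besides ANGPTL4 reached 1 RPKM in either library, and the remaining member was not assessed.

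Apart from ANGPTL4, most of the transcriptome was similar in the 2 libraries. For 96.9% of measured genes, those with at least 1 RPKM in at least 1 library, the values differed by less than 2-fold on the log2(RPKM + 1) scale, which is used for every 2-fold count. Across these genes, which are not independent replicates, Pearson's r of log2(RPKM + 1) was 0.967 and Spearman's rho was 0.960. At least 2-fold higher values in the ANGPTL4 library were found for 141 genes, and at least 2-fold lower values for 226 genes. Part of such counts can arise from counting error. Among the 14871 genes with a settled exon length, 59 were higher and 168 lower. In 100 draws with equal levels the medians were 17 and 19, and the highest counts 26 and 27. Of the 226 lower genes, 163 were nuclear protein-coding genes, against 28 of the 141 higher genes, which held 98 rows with clone-based names and 12 pseudogenes. The lower genes held 50 rows with clone-based names and 7 pseudogenes. The median log2 ratio of all measured genes was -0.11. After centring on the median gene, 182 genes were higher and 140 lower, and after upper-quartile scaling 180 were higher and 136 lower, so which direction held more genes depended on the scaling.

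**Figure D1:**
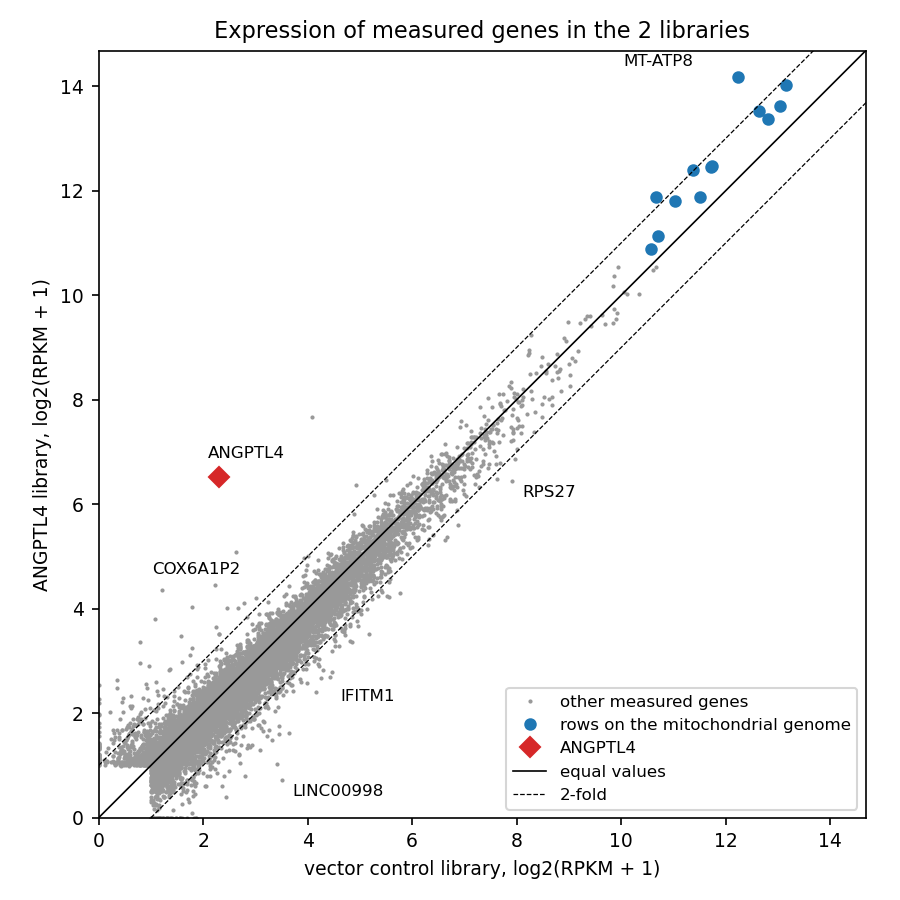
Each point is 1 of the 11802 measured genes, with log2(RPKM + 1) in the vector control library on the x axis and in the ANGPTL4 library on the y axis. The solid line marks equal values and the dashed lines mark 2-fold. ANGPTL4 (diamond) lies far above the diagonal at 3.92 and 91.2 RPKM, and the 13 mitochondrially encoded genes (circles) lie above it at the top of the range.

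Among the genes with at least 10 RPKM in either library that had the lowest log2 ratios, PRDX3, a mitochondrial peroxiredoxin, was at 35.2 RPKM in the control and 10.5 RPKM in the ANGPTL4 library (ratio 0.298, 0.243 to 0.363), and GSTO1, a glutathione transferase, at 28.0 and 9.33 RPKM. The interferon-induced membrane protein IFITM1 (chromosome 11, 313506 to 315272) was at 20.4 and 5.44 RPKM (ratio 0.266, 0.156 to 0.431). The annotated region of IFITM2 covers that of IFITM1, and IFITM2 went the other way, from 2.68 to 6.63 RPKM, so reads of this pair are uncertain. LINC00998 (chromosome 7, 112756773 to 112758668) had the lowest log2 ratio of this class, -2.78, with 129 reads in the control and 4 in the ANGPTL4 library. GNG10, a G protein gamma subunit, was at 11.5 and 2.07 RPKM, and PPP3R1, the regulatory subunit of calcineurin, at 21.2 and 5.89 RPKM. FAM96A was at 17.0 and 4.33 RPKM and OSTC, a subunit of the oligosaccharyltransferase, at 26.9 and 9.37 RPKM. The splicing protein gene SNRPE was at 18.6 and 6.08 RPKM and the ribosomal protein gene RPS27 at 240.3 and 86.0 RPKM. RPL36A-HNRNPH2, a read-through transcript, was at 53.2 and 18.7 RPKM.

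The genes with the highest ratios after ANGPTL4 included more pseudogenes and read-through transcripts. COX6A1P2 (chromosome 6, 37012607 to 37013177), a processed pseudogene, was at 1.33 RPKM in the control and 19.5 RPKM in the ANGPTL4 library (ratio 14.6, 5.72 to 47.8, from 5 and 36 reads). The pseudogenes RPL15P3 and RPL18AP3 were at 1.12 and 13.1 RPKM and at 2.43 and 15.4 RPKM. NDUFC2-KCTD14 and PALM2-AKAP2, which are read-through transcripts, were at 5.20 and 33.0 RPKM and at 3.77 and 11.6 RPKM. POLR2J2, which has near-identical paralogues, was at 5.32 and 15.2 RPKM. NDUFA7, a subunit of respiratory complex I, was at 14.4 and 30.2 RPKM, summed over 2 rows of that name. Reads of pseudogenes, read-through transcripts and near-identical copies can be divided among loci in more than 1 way, so these values are uncertain. That limit extends to lower genes, since 27.0% of the 163 lower nuclear protein-coding genes have a pseudogene named after them. The 12 highest genes also included 3 mitochondrial genes.

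The mitochondrially encoded and the nuclear lists of respiratory chain genes had medians of opposite sign. All 13 mitochondrially encoded genes were higher in the ANGPTL4 library. Their median log2 ratio was 0.74 (percentile 100), and it was above 0 under every scaling tried. Of 10000 random lists of the same size from the same expression bins, 95% lay between -0.33 and 0.12. Matching by bins is loose here, since the 13 genes, at 1512 RPKM or more in both libraries, lie at the top of the range. MT-ATP8, a subunit of ATP synthase, was at 4811 RPKM in the control and 18507 RPKM in the ANGPTL4 library (ratio 3.85, 3.73 to 3.96). MT-ND6 was at 1623 and 3770 RPKM and MT-ND2 at 2668 and 5361 RPKM, both subunits of complex I. MT-ATP8 overlaps MT-ATP6, so part of its reads is uncertain. The mitochondrially encoded genes held 5.11% of reads in the control library (95% Wilson interval 5.10 to 5.13) and 8.71% in the ANGPTL4 library (8.68 to 8.74). Nuclear genes of oxidative phosphorylation were lower for 22 of 26 measured members, with a median of -0.52 (percentile 0), while 4 members, and NDUFA7 outside the list, were higher. SDHC, a membrane anchor of succinate dehydrogenase, was at 23.1 and 8.75 RPKM (ratio 0.379, 0.339 to 0.422), and COX5A, a subunit of cytochrome c oxidase, at 58.9 and 32.2 RPKM.

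Cytosolic ribosomal protein genes were lower for 31 of 35 members, 3 of them at least 2-fold, with a median log2 ratio of -0.47 (percentile 0). RPS27A was at 117.2 RPKM in the control and 47.7 RPKM in the ANGPTL4 library (ratio 0.407, 0.368 to 0.449), and RPS14 at 100.2 and 40.7 RPKM. The list was not uniform, since RPL11 was at 307.9 and 599.2 RPKM. Ribosomal protein genes have many processed pseudogenes, which makes the level of any single member uncertain.

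**Figure D2:**
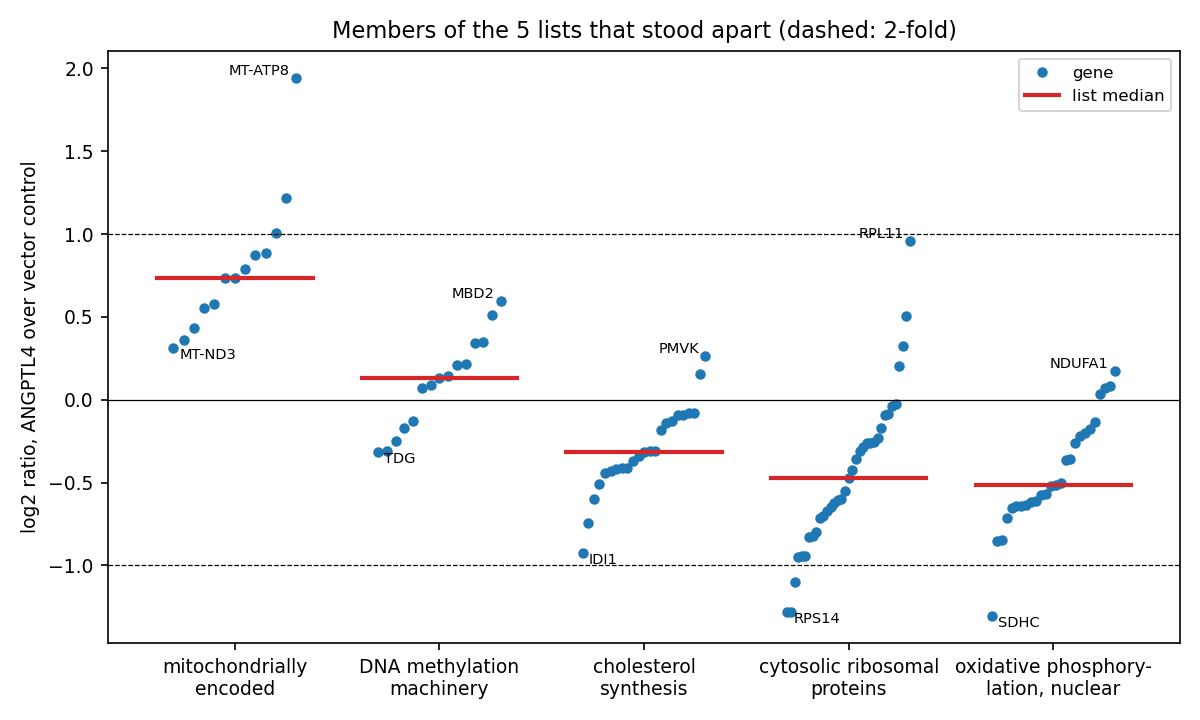
Each point is a measured gene of 1 of the 5 lists whose median stood apart from random lists, with its log2 ratio of the ANGPTL4 library over the vector control on the y axis. Horizontal bars are list medians and dashed lines mark 2-fold. The mitochondrially encoded genes all lie above 0 (median 0.74), while most nuclear oxidative phosphorylation genes (median -0.52) and ribosomal protein genes (median -0.47) lie below it.

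Of the 4 lipid lists, cholesterol synthesis alone stood apart, and not under every alternative. Of 23 cholesterol synthesis genes, 21 were lower in the ANGPTL4 library, none of them 2-fold on the log2(RPKM + 1) scale, with a median log2 ratio of -0.32 (percentile 0.78). After correction for exon length and GC content, which raised the median of all genes by 0.12, the median was -0.16 and the percentile 1.79, and with a minimum of 5 RPKM the percentile was 1.26, so the list no longer stood apart. IDI1, the isopentenyl diphosphate isomerase, was at 12.2 RPKM in the control and 5.95 RPKM in the ANGPTL4 library, and HSD17B7 at 1.55 and 0.525 RPKM, log2 ratios of -0.92 and -0.74 on that scale. PPAR-regulated lipid genes had a median of -0.16 (percentile 26.0). FABP5, a fatty acid binding protein, was at 8.50 and 3.28 RPKM (ratio 0.386, 0.233 to 0.612), and was the only member of that list with a 2-fold difference. The median was -0.18 for fatty acid synthesis (percentile 21.7), where ELOVL1, a fatty acid elongase, had a ratio of 0.565 (0.471 to 0.675), and -0.03 for lipoprotein and lipase handling (percentile 78.5).

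The DNA methylation machinery list, fixed because the series concerns epigenetic silencing, was higher for 10 of 15 members, with a median log2 ratio of 0.13 (percentile 99.6). Besides DNA methyltransferases the list named other genes, among them TET1, TET2, TET3, TDG, EZH2, SUZ12 and EED. Its median therefore does not describe the DNA methyltransferases alone. MBD2, which binds methylated DNA, was at 9.03 RPKM in the control and 14.1 RPKM in the ANGPTL4 library (ratio 1.57, 1.30 to 1.88), and the methyltransferase DNMT3A at 3.26 and 5.07 RPKM (ratio 1.55, 1.30 to 1.85). No member differed 2-fold. The direction depended on scaling, since the median was -0.033 when values were rescaled to a fixed total per library, although its percentile was then 99.4. With correction for exon length and GC content the percentile was 98.6, below the limit of 99.

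Inflammatory and immediate early genes held members on both sides. The list of NF-kB targets and cytokines had a median log2 ratio of 0.01 (percentile 96.8), but stood apart at 0.21 after correction for exon length and GC content, at 0.11 with a minimum of 5 RPKM and at -0.11 after rescaling to a fixed total, each above percentile 99. CCL20, a chemokine, was at 3.76 RPKM in the control and 7.18 RPKM in the ANGPTL4 library, whereas PTGS2, the inducible cyclooxygenase, was at 32.2 and 16.5 RPKM (ratio 0.513, 0.448 to 0.585). Immediate early and ERK feedback genes had a median of 0.03 (percentile 96.8), or 0.23 and above percentile 99 after the same correction, with the transcription factor EGR1 at 11.5 and 20.7 RPKM (ratio 1.79, 1.48 to 2.17) and FOS at 0.423 and 1.24 RPKM. Interferon-stimulated genes had a median of -0.10 (percentile 56.2), with 1 member at least 2-fold higher, IFITM2, and 2 lower, IFITM1 and IFIT2, the latter at 2.57 and 0.532 RPKM. Antigen presentation genes had a median of -0.17 (percentile 26.7), with the immunoproteasome subunit PSMB10 at 10.3 and 6.34 RPKM.

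Of the proliferation and survival lists, none stood apart. Mitosis genes came closest, with 21 of 29 members lower and a median log2 ratio of -0.27 (percentile 1.27). The median was -0.18 (percentile 0.86) when values were rescaled without mitochondrial, ribosomal protein and small RNA genes, and -0.051 (percentile 20.6) after correction for exon length and GC content. The centromere protein CENPA was at 10.1 RPKM in the control and 4.68 RPKM in the ANGPTL4 library, and the kinetochore gene NDC80 at 16.1 and 8.33 RPKM. S-phase genes had a median of -0.13 (percentile 43.8), with RFC3, a replication factor C subunit, at 10.4 and 4.63 RPKM and the flap endonuclease FEN1 at 7.92 and 4.49 RPKM. The medians were -0.21 for p53 targets (percentile 11.7) and -0.11 for apoptosis regulators (percentile 48.5), where BID was at 6.75 and 3.85 RPKM. Replication-dependent histones had a median of -0.03 (percentile 75.1).

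The stress lists and the remaining metabolic lists stayed within percentiles 1 to 99. ATF4 targets of amino acid stress had a median log2 ratio of -0.29 (percentile 2.26), with MTHFD2, an enzyme of mitochondrial folate metabolism, at 39.2 RPKM in the control and 23.0 RPKM in the ANGPTL4 library and SLC3A2 at 68.0 and 40.7 RPKM. Heat shock genes had a median of -0.29 (percentile 4.67), with the chaperonin HSPD1 at 237.2 and 146.9 RPKM. NRF2 targets had a median of -0.24 (percentile 8.80), with CBR1 at 9.31 and 4.17 RPKM. GPX2 was at 1.51 and 0.440 RPKM, from 14 and 2 reads, a ratio of 0.290 (0.0320 to 1.26). The unfolded protein response list had a median of -0.16 (percentile 25.4), with SEC61B at 30.3 and 11.7 RPKM and XBP1 at 20.5 and 12.1 RPKM. Hypoxia response genes had a median of -0.17 (percentile 18.6) and glycolysis genes -0.09 (percentile 53.1). Among them the glycolytic enzymes ENO2, PGK1, LDHB and ENO1 were at 8.85 and 4.48, 67.2 and 39.0, 193.3 and 120.1, and 391.8 and 258.3 RPKM. Metallothioneins had a median of -0.33 (percentile 9.73), with MT1X at 98.2 and 38.7 RPKM (ratio 0.394, 0.338 to 0.458). Drug efflux and xenobiotic genes had a median of -0.07 (percentile 60.9), with GSTM3 at 2.58 and 0.895 RPKM. The housekeeping reference list had a median of -0.20 (percentile 11.2), and its member PPIA was at 173.0 and 102.4 RPKM.

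Epithelial identity and adhesion lists lay close to the random lists. Epithelial junction and keratin genes had a median log2 ratio of -0.09 (percentile 57.3), with the tight junction gene CLDN4 at 35.5 RPKM in the control and 23.1 RPKM in the ANGPTL4 library. Urothelial luminal genes had a median of 0.00 (percentile 89.2), with PPARG at 6.09 and 4.13 RPKM and GATA3 at 13.1 and 15.8 RPKM. Basal and squamous genes had a median of -0.10 (percentile 49.5). In that list S100A8, a calcium-binding protein of inflamed epithelium, was at 12.4 and 5.84 RPKM and KRT1 at 0.917 and 1.99 RPKM. S100A7 was at 2.55 RPKM from 9 reads in the control and listed at 0 in the ANGPTL4 library, a difference not detectable at this depth since the interval of the ratio included 1. Mesenchymal genes had a median of 0.07 (percentile 96.7), integrins and focal adhesion genes -0.03 (percentile 81.5), and matrix and basement membrane genes 0.01 (percentile 94.9). Matrix proteases and inhibitors had a median of -0.24 (percentile 5.05), with the urokinase receptor PLAUR at 25.2 and 16.4 RPKM.

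Angiogenic factors had a median log2 ratio of -0.10 (percentile 53.9). Endothelin-1, EDN1, was at 5.76 RPKM in the control and 1.98 RPKM in the ANGPTL4 library (ratio 0.343, 0.175 to 0.622), and FGF2 at 2.63 and 1.28 RPKM (ratio 0.486, 0.310 to 0.740). TGF-beta targets had a median of 0.04 (percentile 97.1), with the receptor TGFBR1 at 10.7 and 6.46 RPKM. Hippo-YAP targets had a median of -0.27 (percentile 4.51), Notch pathway genes -0.17 (percentile 31.6) and Wnt targets -0.14 (percentile 39.4), where the secreted inhibitor DKK1 was at 18.0 and 10.2 RPKM.

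Few markers of other cell types were measured. At least 1 RPKM was reached by 4 fibroblast, 1 endothelial, 3 leukocyte, 4 neural, 1 hepatocyte and 2 haematopoietic markers and by 1 cancer-testis gene, too few for a percentile. Among them CD68 was at 17.1 RPKM in the control and 18.0 RPKM in the ANGPTL4 library, LAPTM5 at 3.39 and 1.98 RPKM, COL1A1 at 4.14 and 4.06 RPKM, EGFL7 at 7.68 and 8.59 RPKM, SERPINA1 at 5.80 and 6.18 RPKM, UCHL1 at 25.6 and 25.7 RPKM and DDX43 at 1.73 and 2.09 RPKM. HBA1 was at 1.64 RPKM from 9 reads in the control and listed at 0 in the ANGPTL4 library, with an interval of the ratio that included 1.

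**Figure D3:**
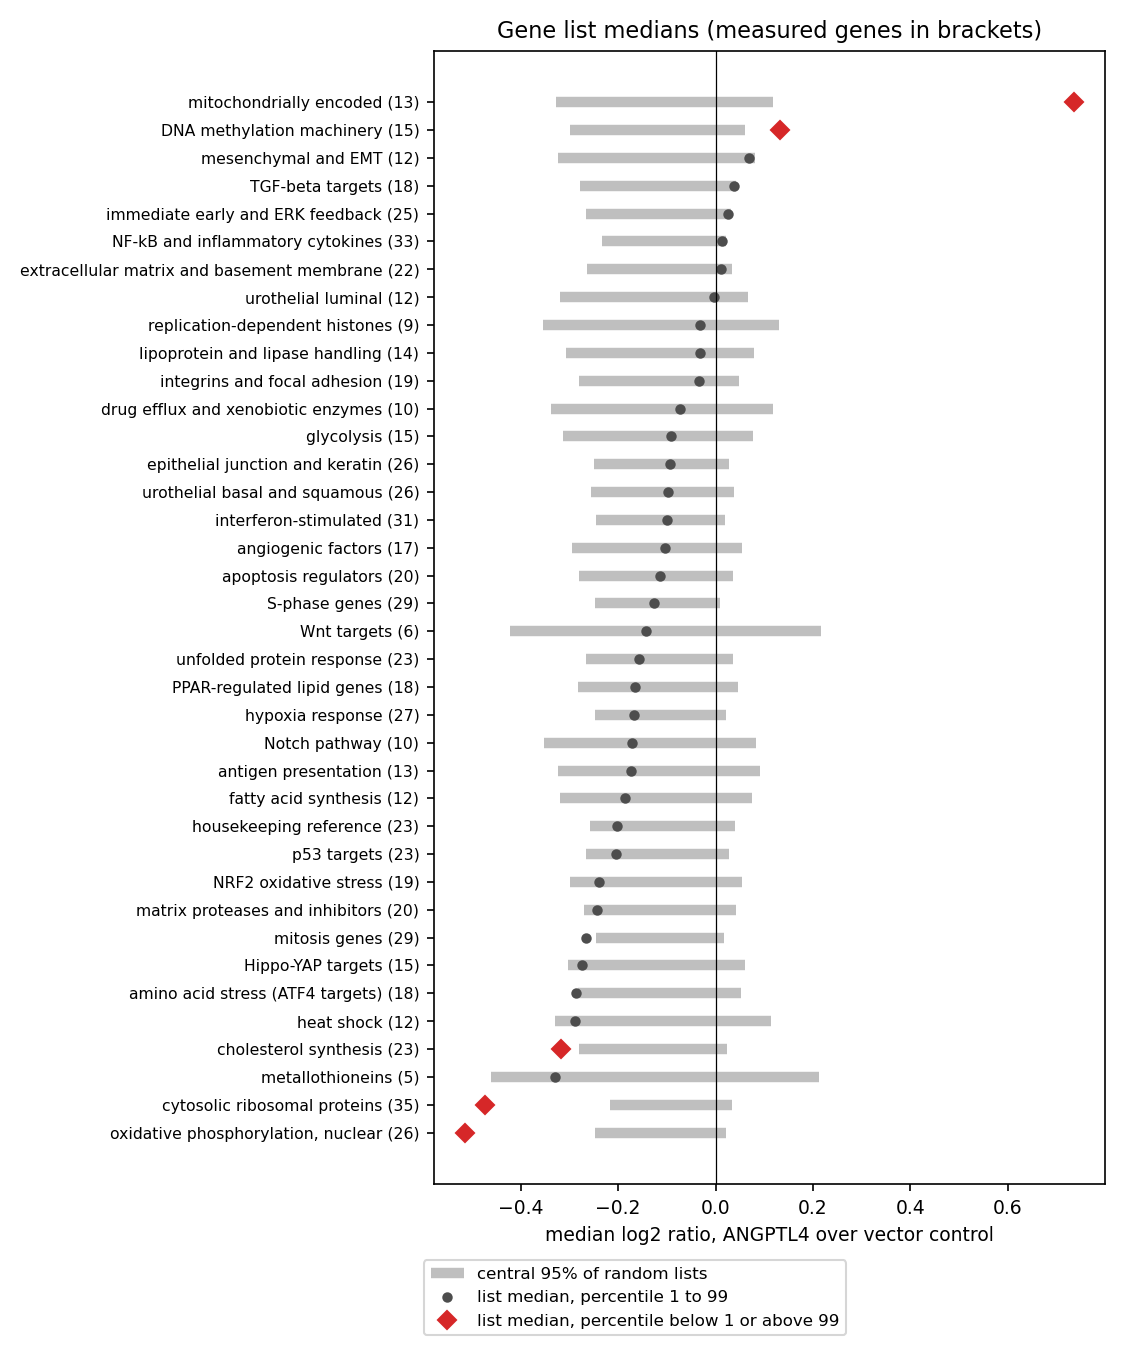
Points are the median log2 ratios (ANGPTL4 library over vector control, x axis) of the 38 gene lists with at least 5 measured members. Grey bars hold the central 95% of 10000 random lists of the same size from the same expression bins. Diamonds mark the 5 lists below percentile 1 or above percentile 99, from -0.52 for nuclear oxidative phosphorylation to 0.74 for mitochondrially encoded genes.

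The percentiles describe these libraries only, and a difference between any 2 cultures of the line, or between stable clones, would enter every value given here. Where the library is shallow, small differences at low genes were not detectable.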

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

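The counts over nuclear protein-coding genes and the correction for exon length and GC content were chosen after the results were seen. The log2 ratio of ANGPTL4 was 3.43 with a pseudocount of 5 and lay between 4.23 and 4.59 under the other alternatives. Genes higher and lower by 2-fold were 141 and 226, also with no minimum and with the highest row per symbol, but these counts moved with other choices: 284 and 532 with a pseudocount of 0.1, 15 and 26 with a pseudocount of 5, 34 and 126 with a minimum of 5 RPKM, 364 and 1092 at a fold limit of 1.5, and 14 and 5 at a fold limit of 4. Scaling gave 140 lower genes after centring and 136 after upper-quartile scaling, with 182 and 180 higher. Rescaling to a fixed total gave 586 and 1386, and without mitochondrial, ribosomal protein and small RNA genes 920 and 1330. Rescaling multiplied the values by 3.55 to 6.05, so the pseudocount and the minimum weighed less and 15150 and 16048 genes were measured. Intervals that do not overlap left 48 and 159 genes, and nuclear protein-coding genes alone gave 28 and 163. The former count left out symbols with several rows and used minimum reads for rows without a settled length. Only 59 of the 141 higher and 168 of the 226 lower genes had a settled length. Genes missing from that count are therefore not all within counting error. The median of all genes shifted by 0.11 with centring, 0.14 with upper-quartile scaling, -0.17 with rescaling to a fixed total and 0.12 with the correction.

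Of 54 alternative values of the 5 lists that stood apart, 50 kept their direction and stayed apart. Cholesterol synthesis was at -0.16 (percentile 1.79) after correction for exon length and GC content and at -0.33 (percentile 1.26) with a minimum of 5 RPKM, which left 18 members. DNA methylation machinery was at 0.19 (percentile 98.6) after the same correction and at -0.033 after rescaling to a fixed total, where the median of all genes is lower too. The cause was not tested. Of 361 alternative values of the other 33 lists, 326 stayed close and 5 stood apart: 0.23 for immediate early genes and 0.21 for NF-kB targets after the correction, 0.11 and -0.11 for NF-kB targets with a minimum of 5 RPKM and after rescaling to a fixed total, and -0.18 for mitosis genes after rescaling without mitochondrial, ribosomal protein and small RNA genes. Another 30 moved and stayed within percentiles 1 to 99: 18 down with rescaling to a fixed total (2 changed sign) and 8 up with upper-quartile scaling (4 changed sign), and 4 up with the correction, each in the direction of the shift of all genes; the 4 are mitosis genes to -0.051, Hippo-YAP targets to -0.080, the housekeeping reference to -0.052 and interferon-stimulated genes from -0.10 to 0.04. Of 1665 alternative values of named genes, 99 moved up and 53 down. None of the 35 named genes with a 2-fold difference changed sign. No library could be left out and no paired analysis was possible because each group has 1 library. Depth limits low genes most, since 9 reads against 0 still gave an interval that included 1.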

Other observations

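Tests of library scaling, one factor for all genes, reads left for nuclear genes and overlapping mitochondrial genes were chosen after the results were seen. So were those of RNA preparation, of exon length and GC content for genes with pseudogenes and of chromosomal blocks. Centring, leaving mitochondrial reads out of the total and summing reads of genes and pseudogenes were judged uninformative only after their outcome was seen. The same holds for the lists matched on the number of named pseudogenes. The genes in the next paragraph were also chosen after their values were seen.

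NEAT1, the long non-coding RNA that builds paraspeckles (chromosome 11, 65190245 to 65213011), was at 44.0 RPKM in the vector control and 87.4 RPKM in the ANGPTL4 library, a ratio of 1.98 (1.92 to 2.05) from 6565 and 6409 reads. OXTR, the oxytocin receptor (chromosome 3, 8792094 to 8811314), had 73 reads in the control and 1 in the ANGPTL4 library, a ratio of 0.0278 (0.000696 to 0.160). Neighbouring or read-through pairs went opposite ways: NDUFC2 was at 16.5 and 7.46 RPKM while NDUFC2-KCTD14 was at 5.20 and 33.0 RPKM, and RPL36A was at 14.6 and 25.8 RPKM while RPL36A-HNRNPH2 was at 53.2 and 18.7 RPKM. RP11-3P17.5, a clone-named row on chromosome 3, was at 16.0 and 202.0 RPKM.

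The higher level of the 13 mitochondrially encoded genes may be technical or biological. Centring gave a median log2 ratio of 0.84 but moves random lists by as much and decides nothing, whereas one factor for all genes is argued against by the median of -0.11 over 11789 nuclear genes (bootstrap interval -0.12 to -0.11), below 0.31, the lowest of the 13. Shared reads of overlapping mitochondrial genes are argued against by a median of 0.66 over the 8 genes without overlap, and GC content by a median of -0.16 over 1774 nuclear genes of like GC content, also below that lowest value. RNA quality or preparation of a library cannot be told apart from the transfection with 1 library per group. An effect of ANGPTL4 stays open and untested in the same way.

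Ribosomal protein genes and nuclear respiratory chain genes, 61 in all, had a joint median of -0.51, below the random range of -0.19 to 0.00. Correction for exon length and GC content gave -0.34, but it also raised the random range (-0.07 to 0.11), and the distance to its lower end went from -0.32 to -0.27, so they are not the whole cause. Leaving mitochondrial reads out of the total gave -0.47, which met the bound set beforehand but decides nothing, since that bound (-0.13) moves with the total as the lists do. The smaller share of reads left for nuclear genes gives each of them a log2 ratio of only -0.056. The bootstrap interval of the joint median was -0.61 to -0.28, so this share is not the whole cause. Of random lists matched on the number of named pseudogenes, 95% lay between -0.28 and -0.08. That match used only the classes of no, 1, 2 to 4 and 5 or more named pseudogenes, and not expression. It therefore cannot exclude pseudogenes as the whole cause. Adding the reads of named pseudogenes left the median of 52 genes at -0.49, but this moved only 3 of the 52 and so cannot decide. Reads lost to pseudogenes therefore stay open as a part or the whole of the cause. RNA quality or preparation, clonal or culture differences and an effect of ANGPTL4 also stay open and were not tested for these genes.

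Pseudogenes made up 8.51% of the higher genes (12 of 141) and 1.23% of measured genes (145 of 11802), but also 7 of the 226 lower genes, more than that share, and genes that have pseudogenes were frequent among the lower ones. These counts may be too low, because gene type was looked up by symbol and clone-named rows such as RP11-3P17.5 can lack one. Clone-named rows were 98 of the higher, 50 of the lower and 620 of the measured genes. Of the 163 lower nuclear protein-coding genes, 27.0% (44 genes) have a pseudogene named after them, against 18.4% at most in random lists matched on expression (95% of them 5.52% to 14.7%) and 22.7% at most in lists matched also on exon length and GC content (8.59% to 18.4%), so the latter are not the whole cause. Lower by 2-fold were 1.23% of genes with no named pseudogene, 3.15% with 1, 5.10% with 2 to 4 and 3.32% with 5 or more, so the share did not rise throughout, and a different division of reads between genes and pseudogene loci in the 2 libraries stays only a candidate explanation. Counting noise is argued against, because among the 14871 genes with known reads 10 of the 12 higher pseudogenes were counted, against at most 5 in 100 draws with equal levels, but not for lower pseudogenes (5, against at most 6). For 6 of 7 higher pseudogenes with a listed parent gene, the parent had at least 10 times the reads and the sum was under 2-fold, but such a parent fixes the sum, so reads shared with the parent gene cannot be told apart from reads of the pseudogene itself, and no biological explanation was tested.

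Stable clones can differ in copy number, and a gained or lost chromosomal block was therefore sought as a hypothesis. The most extreme runs of 25 neighbouring genes had medians of -0.44 (chromosome 7, 107383262 to 124570037) and 0.19 (chromosome 19, 53935227 to 55669141). Runs as extreme as the highest arose in 15.0% of 1000 shuffles of gene order and as extreme as the lowest in 15.3%. No block beyond chance was therefore found at this window size. Medians of the autosomes and X lay between -0.16 (chromosome 13) and -0.06 (chromosome 21). Which blocks the search could detect was not tested.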
